A study of Homo sapiens with 12 samples.

How the data were processed

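Transcript levels were measured in K562 cells at 6 times after the addition of 50 µM hemin, with 2 cultures per time and 1 Affymetrix human genome array per culture, 12 arrays in all. The values are intensities, deposited by the authors as MAS 5.0 signals per probe set on a linear scale, and per the labels MAS 5.0 was the expression analysis, with no settings stated. The deposited values are never negative and hold no missing cells, and the mean of each array after trimming 2% at both ends is the same to within rounding, 150.05 or 150.06, as a scaling of every array to 1 target gives. The depth of an array is its signal over background. No detection calls were used here, so a dim signal is uncertain, and the number of arrays limits the precision.

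The signals were taken as log2(signal + 10.2), where 10.2 is the 25th percentile of all values of the table, with no further normalization. This constant makes the folds of dim genes smaller than the ratios of their signals. Control probe sets (68 of 22283) were left out of the tests. Probe sets above 39.9, the median of all values, on at least 2 of the 12 arrays were kept, which left 12642. Of these, 11155 are annotated to 1 gene, 668 to several genes and 819 to none. The last 2 kinds were tested but not named and not counted as genes. Each of the 7489 genes is represented by its probe set with the highest mean signal, and 2468 genes had more than 1. For the named genes there are 103 values of other probe sets. Of these, 2 have the opposite sign and 23 are under 50% of the log2 change given, and they are printed beside it. For HBA1 and HBA2, HBG1 and HBG2, and HSPA1A and HSPA1B the probe sets are annotated to several genes, and FTH1 is not in the annotation, so these genes were not analysed here. Probe sets that can bind transcripts of related genes carry _s_at or _x_at in their names and were kept. No symbol of the annotation needed an update. No genome build is named with the array, so probe positions are not given.

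A linear model with 1 mean per time was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the intensity (6 residual and 7.98 prior degrees of freedom). Contrasts were each later time minus 0 h, the mean of 48 and 72 h minus the mean of 6 and 12 h, and a moderated F test over the first 5. Tests are two-sided, p values were adjusted by Benjamini and Hochberg over the 7489 genes of a contrast, and a gene was called with an adjusted p under 0.05. The 29 gene lists hold 617 entries, of which 472 have a value. They cover erythroid genes, iron and heme, stress responses, growth, metabolism and markers of other blood lineages. The 28 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 168 tests of lists and contrasts. The lymphocyte list is given as values. The counts adjusted over the list alone use the same p values adjusted within the list. The samples, contrasts, filter, constant, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

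The rule names HMOX1, TXNRD1, GCLM, NQO1, SLC7A11, FTL, TFRC, HBZ, HBE1, ALAS2, GATA1, KLF1 and MYC at 72 h. It adds the 10 largest rises and falls at 72 h, and the 5 largest rises and falls at each other time and for late minus early, among called genes whose arrays of both sides do not overlap. In each list it adds up to 4 members with the largest absolute change at the time with most called members. Values of named genes at other times, and the few genes that fall outside the rule, were chosen after the values were seen.

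The alternatives were other constants, no filter and a stricter one (mean above 69.3, the 60th percentile), quantile normalization, median centring, variance models without the intensity trend or with robust estimation, the arrays of a contrast alone, another probe set per gene, the culture letter as a block, and leaving out each array in turn. The ACTB ratio as a covariate was added after the data were seen. When an array was left out, the lone array of its time was assumed to vary like the other groups. The correlations between cultures use log2 changes from 0 h across genes and carry no p. The procedure was tested on simulated data, with changes added at 72 h to some of 7395 tested genes. It recovered 37.3% of 67 genes with a log2 change of 0.5, 80.6% of 67 with a change of 1 and 90.9% of 66 with a change of 2. Another 26 genes, of the proteasome list, were raised by 0.5, and 17 of them were called. It called 9 unchanged genes among 165 calls, and 0 genes at 6 h, where nothing was added. The simulated values were drawn independently for each probe set and array, with no drift of array quality and few changed genes. These shares may therefore not hold for the real arrays.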

Results

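K562 cells, a human erythroleukaemia line that can make embryonic and fetal haemoglobin chains, were cultured with 50 µM hemin, the iron-bound porphyrin of haemoglobin in its oxidised form, for 0, 6, 12, 24, 48 or 72 h. Each of the 6 times had duplicate cultures, A and B, and each culture was measured on its own Affymetrix human genome array. The data are 12 arrays of 22283 probe sets. The signal scale was the same on all arrays, with a trimmed mean of 150.05 or 150.06, and the median signal ranged from 34.4 on array 6 h B to 44.6 on array 48 h B. The number of probe sets above the median of the whole table, 39.9, ranged from 10551 to 11697 per array. The highest signal was 17014 on array 48 h A and between 7832 and 11686 on the other arrays. The log2 ratio of the 3' to the 5' probe set of ACTB, a sign of RNA quality, was -0.0046 ± 0.11 at 0 h (mean ± SD, n = 2), 0.32 ± 0.11 at 6 h, 0.074 ± 0.0032 at 12 h, 0.15 ± 0.055 at 24 h, 0.40 ± 0.064 at 48 h and 0.59 ± 0.15 at 72 h. The same ratio of GAPDH was -0.30 ± 0.0079 at 0 h, -0.20 ± 0.13 at 6 h, -0.16 ± 0.031 at 12 h, -0.17 ± 0.047 at 24 h, -0.32 ± 0.22 at 48 h and 0.011 ± 0.057 at 72 h. The course holds no untreated culture after 0 h, so hemin and time in culture are not separated, and 2 arrays per time limit the precision of every value. Signals are given as means ± SD of the 2 arrays of a time and log2 changes with the SE of the fit.

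The first question is which transcripts changed at any time of the course. The embryonic globin chain gene HBZ rose at each of the 5 later times, from a signal of 749 ± 11.5 at 0 h to 1484 ± 16.3 at 6 h, 3419 ± 159 at 24 h and 6086 ± 1437 at 48 h, and was at 4488 ± 4.81 at 72 h. NQO1, a quinone reductase induced by electrophiles, rose from 580.0 ± 33.7 to 3634 ± 226, and OSGIN1, an oxidative stress response gene, from 38.4 ± 3.75 to 957 ± 63.2. GCLM, a subunit of the enzyme that starts glutathione synthesis, had a signal of 570.4 ± 74.3 at 0 h and 2708 ± 162 at 72 h. The chemokine gene CXCL8 was at 52.8 ± 12.1 at 0 h and 75.3 ± 2.97 at 12 h, then at 2070 ± 195 at 24 h and 6751 ± 1428 at 48 h. MCM5, a subunit of the replicative helicase, went from 519.9 ± 26.3 to 4289 ± 88.3, and SLC30A1, a zinc exporter, from 745 ± 36.0 to 108 ± 0.0707. In the moderated F test of limma over the 5 contrasts with 0 h, 4138 of 7489 genes passed (55.3%).

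**Figure D1:**
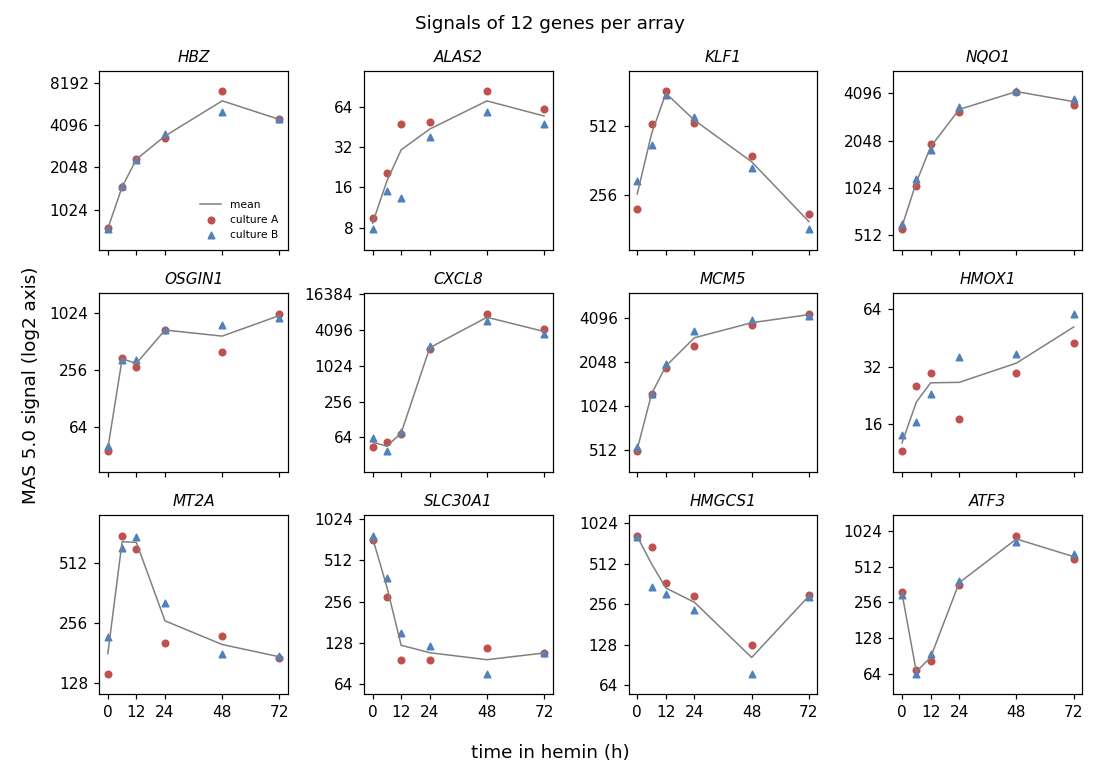
Signal of 12 named genes on a log2 axis against hours with hemin, with points for cultures A and B and a grey line through their mean. CXCL8 goes from 52.8 ± 12.1 (SD, n = 2) at 0 h to 6751 ± 1428 at 48 h, while KLF1 goes from 258 ± 50.8 to 710.2 ± 19.3 at 12 h and is at 196 ± 20.5 at 72 h.

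The number of genes called against 0 h was 515 at 6 h, 1060 at 12 h, 1247 at 24 h, 2556 at 48 h and 2443 at 72 h. In fits of the arrays of a contrast alone the counts were 563, 1410, 1269, 1819 and 3070. The order of 12 and 24 h, and that of 48 and 72 h, thus depends on the fit. At 72 h 1342 genes rose and 1101 fell, with 390 rises and 197 falls of at least 2-fold, but after median centring 1209 rose and 1256 fell. All these contrasts share the 0 h arrays, and their overlap is therefore not used as evidence. Camera with a preset correlation called 13 lists at 6 h, 13 at 12 h, 12 at 24 h, 11 at 48 h and 13 at 72 h. Of these, 6, 7, 4, 3 and 6 held with an estimated correlation. With each list taken once, at the time with most called members, the calls that held with an estimated correlation were those of the metallothioneins, the NRF2 and BACH1 targets, the integrated stress response, cholesterol synthesis, the globins and glycolysis. Some calls at other times of a list held as well.

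**Figure D2:**
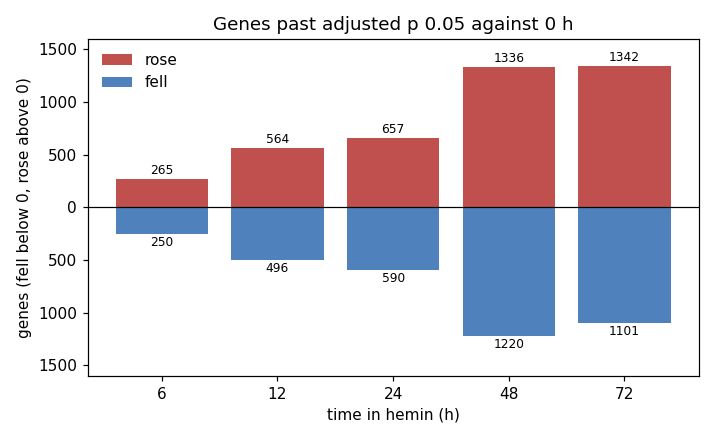
Number of genes called in limma at each time against 0 h, with rises above the zero line and falls below it. The count is 515 at 6 h (265 rises, 250 falls) and 2443 at 72 h (1342 rises, 1101 falls).

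The comparison of 6 h with 0 h asks what changed first after hemin was added. The metallothioneins, small proteins that bind zinc and copper, rose: 6 of 8 tested genes rose, 1 fell and 1 did not pass (6 rose and 1 fell adjusted over the list alone), with median log2 change 1.54, camera adjusted p = 4.87e-05 and adjusted p = 0.0463 with an estimated correlation. MT2A rose 3.57-fold (log2 change 1.84 ± 0.21), from 179 ± 52.5 to 653 ± 63.6, and MT1G rose 2.97-fold (1.57 ± 0.23). MT1H rose by 2.89 ± 0.51 and MT1X by 1.66 ± 0.32 on the log2 scale. The probe sets of MT2A, MT1G, MT1H and MT1X are all _x_at ones, which can bind transcripts of related genes. Their rises may therefore not be separate. The member of the list that fell was SLC30A1, a zinc exporter and not a metallothionein, at -1.18 ± 0.22. NRF2 and BACH1 targets, genes of the antioxidant response, also rose: 9 of 18 tested genes rose, 0 fell and 9 did not pass (9 rose and 0 fell adjusted over the list alone), with median log2 change 0.42, camera adjusted p = 3.64e-07 and adjusted p = 0.0438 with an estimated correlation. OSGIN1 rose 7.13-fold (2.83 ± 0.22) and GCLM 2.93-fold (1.55 ± 0.13). The globin list rose as well: 3 of 6 tested genes rose, 0 fell and 3 did not pass (5 rose and 0 fell adjusted over the list alone), with median log2 change 0.90, camera adjusted p = 2.09e-05 and adjusted p = 0.0399 with an estimated correlation.

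Genes of the integrated stress response, which cells switch on when amino acids or heme are short or proteins misfold, fell at 6 h: 0 of 25 tested genes rose, 8 fell and 17 did not pass (0 rose and 10 fell adjusted over the list alone), with median log2 change -0.24, camera adjusted p = 3.11e-08 and adjusted p = 0.0343 with an estimated correlation. CHAC1, a glutathione-degrading enzyme of this response, fell 4.73-fold (-2.24 ± 0.22) and the transcription factor gene ATF3 fell 4.11-fold (-2.04 ± 0.13). The immediate early genes fell as a group: 0 of 11 tested genes rose, 4 fell and 7 did not pass (0 rose and 5 fell adjusted over the list alone), with median log2 change -0.21, camera adjusted p = 4.07e-04 and adjusted p = 0.0447 with an estimated correlation. EGR1 fell 4.0-fold (-2.0 ± 0.16), with a second probe set at -0.52. Among the hypoxia response genes, 0 of 13 tested genes rose, 5 fell and 8 did not pass (0 rose and 7 fell adjusted over the list alone), with median log2 change -0.49, camera adjusted p = 1.69e-07 and adjusted p = 0.0343 with an estimated correlation. PIK3CG, a phosphoinositide kinase gene, fell 7.41-fold (-2.89 ± 0.32), from 112 ± 4.95 to 6.25 ± 1.06, and the glucose transporter gene SLC2A3 fell 4.25-fold (-2.09 ± 0.16). Of the lymphocyte markers, 2 genes were tested, too few for camera. CD3D fell at -0.77 ± 0.15, also when adjusted over the list alone, and CD3E was at -0.88 ± 0.42 (adjusted p = 0.238). ZNF335 and DUS2 rose by 2.15 ± 0.48 and 1.97 ± 0.50, with 0 h signals of 14.8 ± 0.141 and 19.6 ± 1.77, while a second DUS2 probe set was at 0.17 (unadjusted p = 0.401).

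At 6 h 265 genes rose and 250 fell, with 43 rises and 57 falls of at least 2-fold. The mean ACTB ratio was higher at 6 h (0.32 ± 0.11) than at 0 h (-0.0046 ± 0.11), and with this ratio as a covariate, chosen after the data were seen, 16 genes passed. Over the 515 genes the median SE went from 0.15 to 0.27 and the median absolute log2 change from 0.71 to 0.62. The count was 109 without array 0 h A, 156 without 0 h B, 273 without 6 h A and 110 without 6 h B. It was 320 without the filter on dim probe sets and 332 without the intensity trend in the variance. The calls of ZNF335 (log2 change 2.0 to 2.30 over the fits with 1 array left out) and DUS2 (1.84 to 2.11) were lost on leaving out any of 0 h A, 0 h B, 6 h A and 6 h B. Those of MT1X (1.63, 1.7 and 1.64) and CD3D (-0.74, -0.80 and -0.73) were lost without 0 h A, 0 h B and 6 h B, in that order, and that of MT1H without 0 h B (2.23). SLC30A1 lost its 6 h call without 0 h A, 0 h B or 6 h A (-1.40 to -0.95). DUS2 also lost its call after quantile normalization (1.94), and ZNF335 and DUS2 without the filter. With 39.9 in place of 10.2 as the constant added to signals, PIK3CG was at -1.72, CHAC1 at -1.39, ZNF335 at 1.36 and DUS2 at 1.30, and all 4 were called.

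The comparison of 12 h with 0 h asks how the early changes went on. Cholesterol synthesis and uptake genes fell: 0 of 16 tested genes rose, 8 fell and 8 did not pass (0 rose and 10 fell adjusted over the list alone), with median log2 change -0.59, camera adjusted p = 8.03e-08 and adjusted p = 0.0343 with an estimated correlation. Other lists called at 12 h held with an estimated correlation too. The globins (median 0.91), the NRF2 and BACH1 targets (0.63) and the red cell membrane and surface genes (0.44) rose. The integrated stress response (-0.26), glycolysis (-0.18) and hypoxia response genes (-0.47) fell. SLC2A3 fell 5.91-fold (log2 change -2.56 ± 0.16), from 1015 ± 81 to 163 ± 12.0, and SLC30A1 fell 5.80-fold (-2.54 ± 0.22). The transcription factor gene EGR1 fell 5.69-fold (-2.51 ± 0.16), with a second probe set at -0.59. PPP1R16B, which encodes a phosphatase regulatory subunit, fell 5.43-fold (-2.44 ± 0.32), and the semaphorin receptor gene PLXNB2 fell 5.34-fold (-2.42 ± 0.44). OSGIN1 rose 6.40-fold (2.68 ± 0.22), the amino acid transporter gene SLC7A8 4.28-fold (2.10 ± 0.21) and the cell cycle transcription factor gene E2F1 3.75-fold (1.91 ± 0.28). A second E2F1 probe set was at 0.58. MT1H rose by 2.48 ± 0.51 and TMEM176A by 2.14 ± 0.45. KLF1, a transcription factor gene of red cell precursors, rose 2.71-fold (1.44 ± 0.15).

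Growth arrest genes fell as a group at 12 h: 0 of 12 tested genes rose, 4 fell and 8 did not pass (0 rose and 4 fell adjusted over the list alone), with median log2 change -0.25, camera adjusted p = 0.0426 and adjusted p = 0.142 with an estimated correlation. At 6 h this list had a median of -0.30, with camera adjusted p = 0.00348 and 0.0639 with an estimated correlation. At 12 h cyclin-dependent kinase inhibitor gene CDKN1C fell 2.33-fold (-1.22 ± 0.19), CDKN1A was at -0.90 ± 0.23, and the cyclin genes CCNG2 and CCNG1 were at -0.82 ± 0.22 and -0.65 ± 0.14. Other CDKN1C probe sets were at -0.53 and -0.49. For the progenitor markers, 1 of 5 tested genes rose, 0 fell and 4 did not pass (1 rose and 0 fell adjusted over the list alone), with median log2 change 0.16 and camera adjusted p = 0.256. The homeobox gene HHEX rose by 0.61 ± 0.14. CD34 was at 0.42 ± 0.25 (adjusted p = 0.296), MYB at 0.16 ± 0.21 (adjusted p = 0.666) and MEIS1 at 0.085 ± 0.23 (adjusted p = 0.856).

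At 12 h 564 genes rose and 496 fell, with 101 rises and 88 falls of at least 2-fold, and the ACTB ratio was 0.074 ± 0.0032. The count of 1060 was 370 without array 0 h A, 450 without 0 h B, 529 without 12 h A and 435 without 12 h B. The growth arrest call was lost without 0 h A (median -0.18), without 12 h B (-0.19), without the filter (-0.14) and with the ACTB ratio as a covariate (-0.21). CDKN1A (-1.02 to -0.79) and CCNG2 (-0.94 to -0.69) lost their calls on leaving out any of 0 h A, 0 h B, 12 h A and 12 h B, CCNG1 without 0 h A (-0.62) or 12 h B (-0.51), and HHEX without 0 h A (0.60), 0 h B (0.63) or 12 h A (0.56). MT1H lost its call without 0 h B (1.81) or 12 h B (2.34), TMEM176A without 12 h B (1.99), and CCNG2 without the filter. With the constant at 39.9 TMEM176A was at 1.1, PPP1R16B at -1.37, PLXNB2 at -1.43 and CCNG2 at -0.50, and all 4 were called.

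The comparison of 24 h with 0 h describes the middle of the course. CXCL8 rose 33.3-fold (log2 change 5.06 ± 0.18), the chemokine gene CXCL3 8.40-fold (3.07 ± 0.19) and the heat shock gene DNAJB4 7.08-fold (2.82 ± 0.24). OSGIN1 rose 14.1-fold (3.82 ± 0.22) and SLC7A8 6.75-fold (2.76 ± 0.21). SLC30A1 fell 6.40-fold (-2.68 ± 0.22) and PPP1R16B 5.85-fold (-2.55 ± 0.32). CD3D, a T cell receptor component, fell 5.50-fold, from 705 ± 23.8 to 121 ± 23.9. IGFBP4, a growth factor binding protein, fell 5.27-fold (-2.40 ± 0.21) and the calcium pump gene ATP2A3 5.27-fold (-2.40 ± 0.24).

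Red cell membrane and surface genes rose as a group at 24 h: 6 of 15 tested genes rose, 0 fell and 9 did not pass (6 rose and 0 fell adjusted over the list alone), with median log2 change 0.42, camera adjusted p = 0.00370 and adjusted p = 0.0639 with an estimated correlation. At 12 h the list had a median of 0.44, with adjusted p = 0.00134 and, with an estimated correlation, 0.0496. The blood group gene KEL rose 2.48-fold (1.31 ± 0.20) and RHD by 0.74 ± 0.16. The anion exchanger gene SLC4A1 was at 0.72 ± 0.34 (adjusted p = 0.171) and EPB41 at -0.77 ± 0.35 (adjusted p = 0.152), with a second EPB41 probe set at -0.34. Among apoptosis regulators, 3 of 13 tested genes rose, 4 fell and 6 did not pass (4 rose and 4 fell adjusted over the list alone), with median log2 change -0.19 and camera adjusted p = 0.724. PMAIP1, which promotes cell death, rose 2.87-fold (1.52 ± 0.14) and the kinase gene PIM1 2.67-fold (1.42 ± 0.14). The initiator caspase gene CASP9 fell 2.0-fold (-1.0 ± 0.12) and the survival gene BCL2L1 2.07-fold (-1.05 ± 0.29). Second probe sets were at 0.67 for PMAIP1 and -0.38 for BCL2L1. At 12 h the apoptosis list had a median of 0.10 and a mean of -0.018. At 48 h its median was -0.11 and its mean 0.047, so that median and mean differ in sign at both times.

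At 24 h 657 genes rose and 590 fell, with 137 rises and 110 falls of at least 2-fold. With the ACTB ratio (0.15 ± 0.055) as a covariate 757 genes passed. The count of 1247 was 537 without array 0 h A, 615 without 0 h B and 623 without 24 h B. BCL2L1 lost its call without 0 h A (-1.04), 0 h B (-1.07) or 24 h B (-0.42) and without the filter, and RHD without 0 h B (0.66). BCL2L1 was at -1.69 without 24 h A. With the constant at 39.9 PPP1R16B was at -1.41.

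At 48 h the NRF2 and BACH1 targets had their largest median. Of this list, 16 of 18 tested genes rose, 0 fell and 2 did not pass (16 rose and 1 fell adjusted over the list alone), with median log2 change 1.60, camera adjusted p = 9.95e-12 and adjusted p = 0.0343 with an estimated correlation. NQO1 rose 7.16-fold (log2 change 2.84 ± 0.10), OSGIN1 11.6-fold (3.54 ± 0.22), GCLM 5.02-fold (2.33 ± 0.13) and ME1, which makes NADPH, 4.71-fold (2.23 ± 0.13). The integrated stress response, lower at 6 h, was higher than at 0 h: 17 of 25 tested genes rose, 0 fell and 8 did not pass (17 rose and 0 fell adjusted over the list alone), with median log2 change 0.80, camera adjusted p = 2.97e-09 and adjusted p = 0.0343 with an estimated correlation. CTH rose 3.38-fold (1.76 ± 0.14), CEBPB 3.34-fold (1.74 ± 0.14), ATF3 2.81-fold (1.49 ± 0.13) and PPP1R15A 2.61-fold (1.39 ± 0.11). This list had turned before 48 h. At 12 h 1 gene rose and 9 fell (median -0.26, camera adjusted p = 9.09e-06, 0.0446 with an estimated correlation). At 24 h 9 rose and 0 fell (median 0.36, camera adjusted p = 2.85e-05, 0.0492 with an estimated correlation). Cholesterol synthesis and uptake genes fell: 0 of 16 tested genes rose, 14 fell and 2 did not pass (0 rose and 14 fell adjusted over the list alone), with median log2 change -0.94, camera adjusted p = 4.73e-11 and adjusted p = 0.0275 with an estimated correlation. HMGCS1 fell 7.44-fold (-2.90 ± 0.26), from 813 ± 13.5 to 103 ± 35.4, with a second probe set at -1.52. INSIG1, IDI1 and DHCR7 fell 3.71-fold, 3.61-fold and 3.22-fold, with a second DHCR7 probe set at -0.74.

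The globin list rose at 48 h: 5 of 6 tested genes rose, 0 fell and 1 did not pass (5 rose and 0 fell adjusted over the list alone), with median log2 change 0.85, camera adjusted p = 8.82e-04 and adjusted p = 0.0523 with an estimated correlation. For heme synthesis, 5 of 11 tested genes rose, 2 fell and 4 did not pass (6 rose and 2 fell adjusted over the list alone), with median log2 change 0.42 and camera adjusted p = 0.420. ALAS2, the first enzyme of the pathway in red cell precursors, rose by a log2 change of 2.08 ± 0.37, from 8.65 ± 1.20 to 70.7 ± 17.6, ABCB6 rose 3.04-fold (1.60 ± 0.15) and FECH 2.18-fold (1.12 ± 0.13). CPOX fell 2.89-fold (-1.53 ± 0.17). For the red cell enzymes, 4 of 10 tested genes rose, 3 fell and 3 did not pass (5 rose and 3 fell adjusted over the list alone), with median log2 change 0.31 and camera adjusted p = 0.431. UBE2O was up 5.02-fold, carbonic anhydrase gene CA1 up 2.44-fold, BLVRB up 1.79-fold and GLRX5 down 1.99-fold. For the erythroid transcription factors, 2 of 12 tested genes rose, 4 fell and 6 did not pass (3 rose and 4 fell adjusted over the list alone), with median log2 change -0.025 and camera adjusted p = 0.519. STAT5B was at -1.07 ± 0.14, LMO2 at -0.91 ± 0.20, STAT5A at -0.80 ± 0.22 and KLF3 at 0.67 ± 0.19. For iron handling, 5 of 12 tested genes rose, 1 fell and 6 did not pass (6 rose and 1 fell adjusted over the list alone), with median log2 change 0.28 and camera adjusted p = 0.121. This list passed without array 48 h B (median 0.43). SLC11A2, an iron importer, rose 2.16-fold, the ferritin chain gene FTL 2.12-fold (1.08 ± 0.17) and PCBP1 1.73-fold, and SLC39A8 was at 0.77 ± 0.19. Other probe sets were at 0.53 and 0.21 for SLC11A2 and at 0.12 for SLC39A8 (unadjusted p = 0.494). The median and the mean of iron handling differ in sign at 6 h (0.11 and -0.012). At 24 h the median (0.055) was above 0 while the direction of the test was down (adjusted p = 0.969), and at 72 h the median was -0.16 and the mean 0.016.

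In the heat shock response at 48 h, 9 of 19 tested genes rose, 2 fell and 8 did not pass (9 rose and 3 fell adjusted over the list alone), with median log2 change 0.17, camera adjusted p = 0.00989 and adjusted p = 0.142 with an estimated correlation. DNAJB4 was up 11-fold, SERPINH1 6.06-fold and DNAJB1 2.46-fold. HSPA1L rose from 6.40 ± 6.65, below the constant of 10.2, to 83.4 ± 12.4, and the size of its log2 change (2.55) depends on the constant. In the unfolded protein response, 9 of 18 tested genes rose, 0 fell and 9 did not pass (11 rose and 0 fell adjusted over the list alone), with median log2 change 0.43, camera adjusted p = 8.63e-04 and adjusted p = 0.119 with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, was up 2.46-fold (1.30 ± 0.098), DNAJB9 up 2.33-fold, HERPUD1 2.23-fold and DNAJC3 2.23-fold. For autophagy, 5 of 18 tested genes rose, 2 fell and 11 did not pass (5 rose and 2 fell adjusted over the list alone), with median log2 change 0.30 and camera adjusted p = 0.0936. SQSTM1 was up 5.67-fold (2.50 ± 0.13), GABARAPL1 5.20-fold, ULK1 3.69-fold and BNIP3L at 0.71 ± 0.19. A second BNIP3L probe set had the opposite sign, at -0.56. Immediate early genes rose: 7 of 11 tested genes rose, 1 fell and 3 did not pass (7 rose and 2 fell adjusted over the list alone), with median log2 change 0.94, camera adjusted p = 0.00305 and adjusted p = 0.0643 with an estimated correlation. IER3 was up 4.01-fold, ZFP36 3.99-fold, DUSP5 2.50-fold and DUSP1 2.24-fold. At 72 h this list had a median of 1.05, with camera adjusted p = 5.12e-05 and 0.0399 with an estimated correlation.

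Oxidative phosphorylation genes fell at 48 h: 0 of 47 tested genes rose, 26 fell and 21 did not pass (0 rose and 28 fell adjusted over the list alone), with median log2 change -0.40, camera adjusted p = 7.51e-09 and adjusted p = 0.173 with an estimated correlation. COX7B fell 2.23-fold, CYC1 2.06-fold, NDUFA8 2.04-fold and SDHA 2.03-fold. For the cytosolic ribosomal proteins, 20 of 50 tested genes rose, 1 fell and 29 did not pass (23 rose and 1 fell adjusted over the list alone), with median log2 change 0.26 and camera adjusted p = 0.00286, but after quantile normalization the direction flipped to a median of -0.12 (adjusted p = 0.0140). The list had adjusted p = 0.593 with an estimated correlation. RPL19, RPS18, RPL32 and RPS12 were at 0.65 ± 0.18, 0.64 ± 0.14, 0.63 ± 0.12 and 0.58 ± 0.13. After quantile normalization they were at 0.29, 0.065, 0.091 and 0.075, where none of the 4 passed. Their 6 h call (median 0.17) was also lost after quantile normalization (median 0.039, adjusted p = 0.355) and with an estimated correlation (adjusted p = 0.432). For the histones, 3 of 11 tested genes rose, 3 fell and 5 did not pass (3 rose and 3 fell adjusted over the list alone), with median log2 change -0.0051 and camera adjusted p = 0.546. H2AC6 was down 1.99-fold, H2BC5 down 1.89-fold, H3-3A at 1.02 ± 0.28 and H3C2 at 0.90 ± 0.23. A second H2BC5 probe set was at -0.16 (unadjusted p = 0.447).

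The other lineages' markers were few. For the megakaryocyte and platelet markers, 0 of 7 tested genes rose, 1 fell and 6 did not pass (0 rose and 1 fell adjusted over the list alone), with median log2 change 0.16 and camera adjusted p = 0.969. Its mean was -0.0081 and the test pointed down, against a median above 0. Integrin gene ITGA2B fell 2.23-fold (-1.16 ± 0.25). GP1BA was at 0.45 ± 0.24 (adjusted p = 0.174), SELP at 0.38 ± 0.28 (adjusted p = 0.322) and ITGB3 at -0.32 ± 0.31 (adjusted p = 0.472), with a second ITGB3 probe set at 0.85. For the granulocyte and monocyte markers, 1 of 4 tested genes rose, 1 fell and 2 did not pass (1 rose and 1 fell adjusted over the list alone), with median log2 change 0.39 and camera adjusted p = 0.858. The transcription factor gene SPI1 was at 1.5 ± 0.35, and the lysozyme gene LYZ at -0.79 ± 0.20. CEBPE was at 0.73 ± 0.42 (adjusted p = 0.196) and ITGAM at 0.048 ± 0.27 (adjusted p = 0.909). Outside the lists, CXCL8 rose 107-fold (6.74 ± 0.18), and the log2 changes of the chaperone gene CLU and the cytokine gene IL1A were 3.71 ± 0.32 and 3.27 ± 0.28. The size of the CLU change depends on the constant, since its signal went from 1.5 ± 0.707 to 143 ± 10.9, and that of IL1A went from 12.8 ± 1.48 to 212 ± 9.83. Second probe sets were at 2.13 for CLU and 0.97 for IL1A. DLK1, a growth-regulating membrane protein, fell 7.07-fold, from 1087 ± 72.8 to 149 ± 51.7. SLC30A1 fell 7.22-fold, SSR3 6.45-fold and CD3D 6.02-fold.

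At 48 h 1336 genes rose and 1220 fell, with 359 rises and 189 falls of at least 2-fold. The balance depends on the scaling, since 1201 rose and 1313 fell after quantile normalization and 1096 rose and 1448 fell after median centring. The ACTB ratio was 0.40 ± 0.064, and with it as a covariate 324 genes passed. For the 2556 genes the median SE went from 0.15 to 0.31 and the median absolute log2 change from 0.69 to 0.68. The count was 1535 without array 0 h A and 1665 without 0 h B. Without 0 h A, LMO2 (-0.66), STAT5A (-0.77), KLF3 (0.69), SLC39A8 (0.71), BNIP3L (0.67), H3C2 (0.88) and SPI1 (1.24) lost their calls. Without 0 h B, STAT5A (-0.83), KLF3 (0.64), RPL19 (0.62) and H3-3A (0.87) did so. Leaving out 48 h A ended the calls of SLC39A8 (0.47), RPL19 (0.32), BNIP3L (0.53), H3-3A (0.57) and SPI1 (0.94), and leaving out 48 h B those of STAT5A (-0.32), KLF3 (0.54), H3C2 (0.69) and LYZ (-0.53). Without 48 h A and still called, ITGA2B was at -0.68, RPS12 at 0.37, STAT5A at -1.27, the heat shock median at 0.11 and the ribosomal protein median at 0.15, and without 48 h B RPL19 was at 0.99. FTL was at 0.43 after quantile normalization, and the immediate early median was 0.31 without the filter. The heat shock median was 0.10 after median centring and 0.47 with the ACTB covariate. With the constant at 39.9 CLU was at 2.14, ALAS2 at 1.18, HSPA1L at 1.42, DNAJC3 at 0.72 and ULK1 at 1.23.

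The comparison of 72 h with 0 h covers the whole exposure. The globin list rose: 6 of 6 tested genes rose, 0 fell and 0 did not pass (6 rose and 0 fell adjusted over the list alone), with median log2 change 1.39, camera adjusted p = 1.62e-04 and adjusted p = 0.0438 with an estimated correlation. HBZ rose 5.92-fold (log2 change 2.57 ± 0.13), the adult beta chain gene HBB 3.54-fold (1.82 ± 0.21), from 79.7 ± 6.22 to 308 ± 28.2, and HBQ1 3.06-fold (1.62 ± 0.35). A second HBB probe set was at 0.84. All HBB probe sets tested are _x_at ones, which can bind transcripts of related genes, so the signal may not be of HBB alone. AHSP, the chaperone of the alpha chain, rose 2.26-fold (1.17 ± 0.26), and the embryonic epsilon chain gene HBE1, bright at 0 h (4410.4 ± 292), was at 0.58 ± 0.17. HBA1 and HBA2, and HBG1 and HBG2, share probe sets and are not separated here, and FTH1 was not analysed here. HMOX1, the heme-degrading enzyme, rose 2.66-fold (1.41 ± 0.33), from 12.8 ± 1.77 to 51.5 ± 12.7, with its mean below the table median of 39.9 at every time before 72 h. The size of this fold depends on the constant added to signals. NQO1 rose 6.17-fold, GCLM 4.70-fold, TXNRD1 2.99-fold and the cystine transporter gene SLC7A11 5.34-fold. ALAS2 rose by a log2 change of 1.77 ± 0.37 and MYC 1.58-fold (0.66 ± 0.15). The erythroid transcription factor gene GATA1 fell 2.07-fold (-1.05 ± 0.14). KLF1 was at -0.37 ± 0.15 (adjusted p = 0.0697), FTL at 0.19 ± 0.17 (adjusted p = 0.436) and the transferrin receptor gene TFRC at -0.39 ± 0.19 (adjusted p = 0.128). A second probe set of FTL was at 0.39 (unadjusted p = 0.0173) and a second one of TFRC at -0.63 (unadjusted p = 3.67e-04).

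For DNA replication at 72 h, 4 of 23 tested genes rose, 8 fell and 11 did not pass (4 rose and 10 fell adjusted over the list alone), with median log2 change -0.19 and camera adjusted p = 0.0842. MCM5 rose 8.11-fold (3.02 ± 0.12). POLA1 fell 2.32-fold (-1.21 ± 0.15), TYMS 1.49-fold and CCNE1 was at -0.57 ± 0.14. For mitosis, 2 of 24 tested genes rose, 5 fell and 17 did not pass (2 rose and 5 fell adjusted over the list alone), with median log2 change -0.15 and camera adjusted p = 0.229. AURKA was down 2.07-fold, CENPA down 1.81-fold, TOP2A down 1.39-fold and PTTG1 at 0.46 ± 0.16. A second AURKA probe set was at -0.27. The MYC and ribosome biogenesis list fell as a group: 1 of 16 tested genes rose, 9 fell and 6 did not pass (1 rose and 11 fell adjusted over the list alone), with median log2 change -0.43, camera adjusted p = 0.00305 and adjusted p = 0.0769 with an estimated correlation. MYC itself rose at this time (0.66 ± 0.15), so the fall was one of other genes. RRP12 was down 1.90-fold, UTP20 1.89-fold, NOP16 1.79-fold and RRS1 at -0.73 ± 0.25. Other RRP12 probe sets were at -0.11 (unadjusted p = 0.624) and -0.52 (unadjusted p = 0.212), and other NOP16 probe sets at -0.87 and -0.10. Proteasome genes rose: 17 of 27 tested genes rose, 0 fell and 10 did not pass (19 rose and 0 fell adjusted over the list alone), with median log2 change 0.34, camera adjusted p = 2.90e-06 and adjusted p = 0.122 with an estimated correlation. PSMB6 was up 2.02-fold, PSMC4 1.82-fold, PSMB7 1.68-fold and PSMD3 1.66-fold. Glycolysis genes fell: 0 of 19 tested genes rose, 8 fell and 11 did not pass (0 rose and 10 fell adjusted over the list alone), with median log2 change -0.28, camera adjusted p = 4.64e-04 and adjusted p = 0.0438 with an estimated correlation. SLC2A3 was down 3.75-fold, ALDOC 2.08-fold, LDHA 1.60-fold and PGAM1 1.59-fold. For the hypoxia response, 4 of 13 tested genes rose, 6 fell and 3 did not pass (4 rose and 6 fell adjusted over the list alone), with median log2 change -0.092 and camera adjusted p = 0.556. EGLN1 was down 3.13-fold, PDK1 down 2.04-fold, P4HA2 up 2.18-fold and ADM at 1.06 ± 0.37.

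With 10.2 added to the signals, the 10 largest rises at 72 h were those of CXCL8 (5.96), OSGIN1 (4.32), the lysosomal protease gene CTSL (3.71), CLU (3.66), CXCL3 (3.31), S100P (3.19), DNAJB4 (3.17), the polyamine catabolism gene SAT1 (3.12), GLRX (3.06) and MCM5 (3.02). The SE of these 10 log2 changes is largest for CLU (0.32), whose signal was 1.5 ± 0.707 at 0 h. The 10 largest falls were those of DLK1 (-3.02), the water channel gene AQP3 (-2.82), CD3D (-2.68), SLC30A1 (-2.68), IGFBP4 (-2.50), ID3 (-2.30), FYB1 (-2.29), MEF2C (-2.29), the receptor kinase gene AXL (-2.29) and ATP2A3 (-2.17). CTSL went from 260.1 ± 8.77 to 3535 ± 184 and AQP3 from 238 ± 21.8 to 24.9 ± 1.13. Other AQP3 probe sets were at -2.0 and -0.52, the latter with unadjusted p = 0.0577.

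At 72 h the ACTB ratio was 0.59 ± 0.15, against -0.0046 ± 0.11 at 0 h, and with it as a covariate 124 genes passed. Among the 2443 genes the median SE went from 0.16 to 0.43 and the median absolute log2 change from 0.71 to 0.78. The count was 1507 without array 0 h A, 1628 without 72 h A and 1503 without 72 h B. HMOX1 lost its call without 72 h B (1.20), and CCNE1 without 0 h A (-0.44). HBE1 lost its call without 0 h A (0.52), 72 h A (0.63) or 72 h B (0.54) and without the filter. ADM (0.86 to 1.27) and RRS1 (-0.86 to -0.61) lost theirs on leaving out any of 0 h A, 0 h B, 72 h A and 72 h B and without the filter. PTTG1 (0.40 to 0.52) lost its call on leaving out any of these or either 12 h array, without the filter, and after median centring (0.42). HBQ1 was at 1.03 without 0 h B and still called. With the constant at 39.9 HMOX1 was at 0.79, ALAS2 at 0.96, CLU at 2.10, ID3 at -1.32, FYB1 at -1.36, AXL at -1.41 and ADM at 0.58. The glycolysis median was -0.44 with the ACTB covariate. KLF1 passed after median centring (-0.42) and without 0 h A (-0.57), TFRC without 48 h A or 48 h B (-0.39 in both), FTL after quantile normalization (0.23), and DNA replication without 0 h B (median -0.23).

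**Figure D3:**
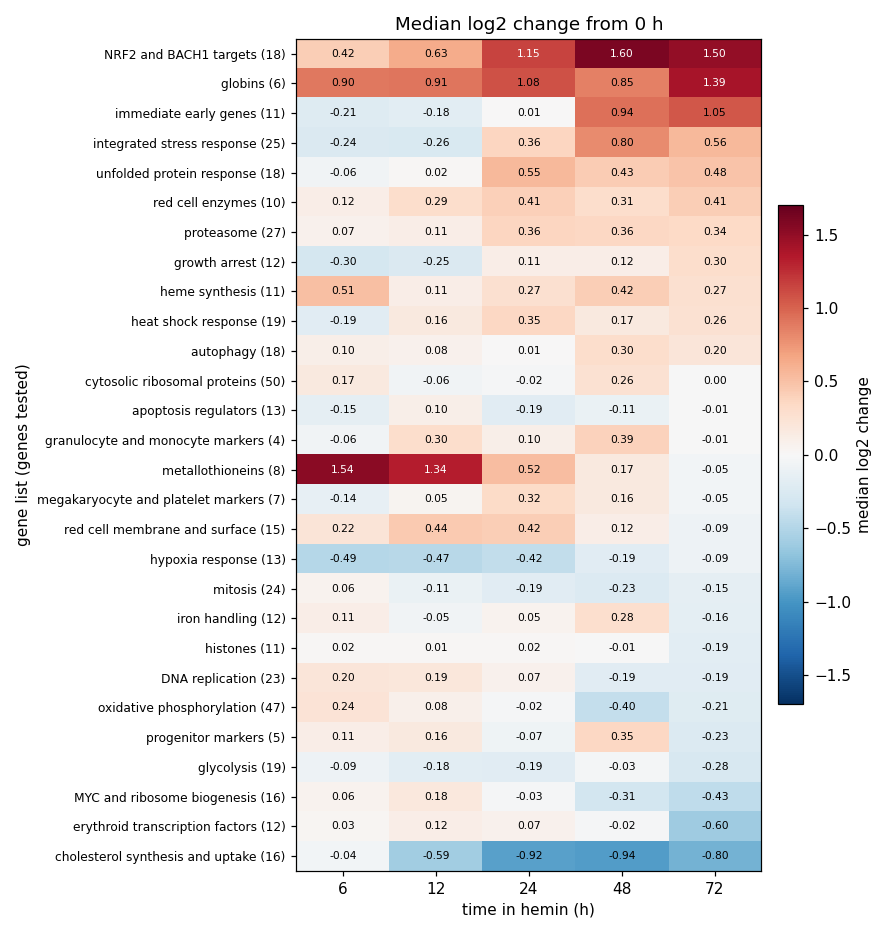
Median log2 change from 0 h of the tested genes of 28 gene lists (rows of the colour map) at each later time (columns). The NRF2 and BACH1 targets go from 0.42 at 6 h to 1.5 at 72 h, cholesterol synthesis from -0.043 to -0.80, and the ribosomal proteins at 48 h are at 0.26, which flips to -0.12 after quantile normalization.

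The comparison of the late times (48 and 72 h) with the early times (6 and 12 h) asks whether both phases of the course differ, without the 0 h arrays. CXCL8 was higher late by a log2 difference of 6.22 ± 0.13, CLU by 3.64 ± 0.22, the stress cytokine gene GDF15 by 3.35 ± 0.11, DNAJB4 by 3.29 ± 0.17 and SAT1 by 3.21 ± 0.07. DLK1 was lower late at -3.02 ± 0.12, MT1H at -2.89 ± 0.36, MT1X at -2.88 ± 0.23, the mucin gene MUC1 at -2.62 ± 0.19 and AQP3 at -2.44 ± 0.14. Other probe sets were at -0.99 and -0.37 for MUC1 and at -1.76 and -1.03 for AQP3. The immediate early genes were higher late: 11 of 11 tested genes rose, 0 fell and 0 did not pass (11 rose and 0 fell adjusted over the list alone), with median log2 change 1.36, camera adjusted p = 1.11e-08 and adjusted p = 0.0275 with an estimated correlation. In the integrated stress response, 22 of 25 tested genes rose, 0 fell and 3 did not pass (22 rose and 0 fell adjusted over the list alone), with median log2 change 0.80, camera adjusted p = 1.60e-14 and adjusted p = 0.0275 with an estimated correlation. ATF3 was at 3.11 ± 0.09 and CHAC1 at 2.69 ± 0.16. In the NRF2 and BACH1 list, 16 of 18 tested genes rose, 0 fell and 2 did not pass (16 rose and 0 fell adjusted over the list alone), with median log2 change 0.62, camera adjusted p = 8.03e-08 and adjusted p = 0.0406 with an estimated correlation. For cholesterol synthesis and uptake, 0 of 16 tested genes rose, 12 fell and 4 did not pass (0 rose and 12 fell adjusted over the list alone), with median log2 change -0.58, camera adjusted p = 1.45e-05 and adjusted p = 0.0438 with an estimated correlation. The metallothionein list, which also holds SLC30A1, was lower late: 0 of 8 tested genes rose, 7 fell and 1 did not pass (0 rose and 7 fell adjusted over the list alone), with median log2 change -1.10, camera adjusted p = 1.75e-04 and adjusted p = 0.0523 with an estimated correlation. Its 48 h change from 0 h had a median of 0.17 and a mean of -0.33, which differ in sign.

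Between late and early times 3383 genes passed, 1671 higher and 1712 lower late, with 262 rises and 120 falls of at least 2-fold, and 14 lists were called, 4 of them with an estimated correlation as well. After quantile normalization 1565 genes were higher and 1888 lower late, and after median centring 1437 were higher and 1988 lower. The ACTB ratio was on average 0.29 higher at the late than at the early times, and with it as a covariate 1109 genes passed, 1074 of them among the 3383. Across the 3383 genes the median SE went from 0.11 to 0.23 and the median absolute log2 difference from 0.54 to 0.58. With the constant at 39.9 the difference of CLU was 2.11.

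The last question is how alike the cultures were. The log2 changes from 0 h in culture A and in culture B were correlated across the tested genes, which are not independent replicates, with Pearson's r of 0.53 at 6 h, 0.65 at 12 h, 0.66 at 24 h, 0.73 at 48 h and 0.81 at 72 h. Spearman's rho at these times was 0.48, 0.60, 0.60, 0.68 and 0.76. Between the change at 6 h in A and that at 72 h in B r was 0.15, and between 72 h in A and 6 h in B it was 0.24. The SD over genes of the log2 difference between the cultures was 0.27 at 0 h, 0.29 at 6 h, 0.30 at 12 h, 0.34 at 24 h, 0.38 at 48 h and 0.26 at 72 h. HBZ at 72 h was at 4488 ± 4.81 in the pair and at 48 h at 6086 ± 1437, and CXCL8 at 48 h at 6751 ± 1428.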

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

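The contrast of late with early times was planned, and the tests of its explanations, and of those for the integrated stress response, were chosen only after the result was seen.

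Between late (48 and 72 h) and early (6 and 12 h) times 3383 genes differed, and in a limma fit of these 8 arrays alone the real split called 2316 genes and was 1 of 35 splits into 4 and 4 with a count as large, the highest of the others being 0. Arrays of a time are alike, and only 3 of the splits keep both arrays of each time on one side, too few for a share under 0.05. Without array 48 h A, the array with the highest signals, 3378 genes passed, which argues against that array as the source. The ACTB ratio differs by 0.25 between 6 and 12 h and by 0.29 between late and early times. If RNA 3' bias, as ACTB measures it, were the whole cause, 6 h minus 12 h would follow late minus early with a slope of 0.85 over these genes. The slope was -0.059 (-0.039 in culture A and -0.083 in culture B), which argues against bias of this kind as the whole cause. A part played by it stays open, since other changes between 6 and 12 h could hide it. The GAPDH ratio, the other measure of RNA quality, was -0.20 ± 0.13 at 6 h, -0.16 ± 0.031 at 12 h, -0.32 ± 0.22 at 48 h and 0.011 ± 0.057 at 72 h. Its late minus early mean of 0.028 lies within this spread, so bias as GAPDH measures it stays open, and at 72 h GAPDH was above the early times as ACTB was. With the ACTB ratio as a covariate 1109 genes passed, since the median SE went from 0.11 to 0.23 while the median absolute log2 difference went from 0.54 to 0.58. Time in culture and hemin stay open, because the design has no untreated late cultures.

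Genes of the integrated stress response were lower at 6 h and higher at 48 h than at 0 h in 22 of 25 cases by sign alone, with 8 of the 25 called down at 6 h and 17 called up at 48 h, and the list differed between late and early times by a median of 0.80. RNA 3' bias, as ACTB measures it, would move the list one way at both times, since the ACTB ratio was above that of 0 h by 0.33 at 6 h and by 0.40 at 48 h, but the median was -0.24 at 6 h and 0.80 at 48 h. With the ACTB ratio as a covariate the median was -0.31 at 6 h and 0.76 at 48 h. Both stayed called in camera with the preset correlation (adjusted p = 1.55e-07 and 3.85e-08), while no value with an estimated correlation is given for this fit. The opposite signs at both times argue against bias of this kind as the whole cause. The GAPDH ratio differed from that of 0 h by 0.098 at 6 h and by -0.021 at 48 h, within the SDs of 0.13 and 0.22, so bias as GAPDH measures it stays open. Array scaling would end the shift under another normalization, but after quantile normalization the late minus early median was 0.85. An effect of time in culture, such as the use of nutrients in the medium, cannot be told apart from hemin, since there are 0 untreated arrays after 0 h.

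Differences between late and early times, each tested in the same contrast, were 6.22 for CXCL8, 3.64 for CLU, 3.35 for GDF15, 3.29 for DNAJB4 and 3.21 for SAT1 on the log2 scale. They were -3.02 for DLK1, -2.89 for MT1H, -2.88 for MT1X, -2.62 for MUC1 and -2.44 for AQP3. The list medians were 0.62 for the NRF2 and BACH1 targets, -0.58 for cholesterol synthesis and uptake and 1.36 for the immediate early genes. The ACTB 3'/5' log2 ratio, which is outside the gene comparisons, was 0.59 higher at 72 h than at 0 h. Of the probe sets without a single gene name, 480 were called at 72 h, and they are unnamed here.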

How the results depend on the processing

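The ACTB ratio as a covariate was chosen after the data were seen, and the other alternatives in this part were planned. Of 190 named gene changes 176 were called, and 144 of these kept their direction and call under each other constant, filter and normalization tried for single genes, with the letter block and with each array left out. Of 28 lists 15 were called, and 13 kept their direction and call under the same choices and with the covariate, while with an estimated correlation 9 of the 15 lost theirs. The count at 6 h (515) was 320 without the filter, which tests more dim genes, and 332 without the intensity trend. The cause of the latter was not tested. With the covariate the counts were 16 at 6 h, 757 at 24 h, 324 at 48 h, 124 at 72 h and 1109 between late and early times, where the SEs were larger. Leaving out 1 array, which leaves fewer samples, gave 109 to 727 genes at 6 h, 370 to 1351 at 12 h, 537 to 1550 at 24 h, 1535 to 2579 at 48 h and 1503 to 2722 at 72 h, with 2824 to 3420 between late and early times and 3295 to 4340 in the F test. Without 0 h A the counts were 109, 370, 537, 1535 and 1507 from 6 to 72 h, and without 0 h B 156, 450, 615 and 1665 from 6 to 48 h. They were 273 without 6 h A and 110 without 6 h B, 529 without 12 h A and 435 without 12 h B, 623 without 24 h B, 1628 without 72 h A and 1503 without 72 h B. Of the named gene changes 29 lost a call on leaving out 1 array, 26 of them without a 0 h array. Most of these named gene changes also lost their call without an array of their own later time, such as SLC39A8 and SPI1 without 48 h A. The highest gene counts at 6, 12, 24 and 72 h and in the F test came from fits without a 48 h array. Fewer samples do not account for these, and the 2 cultures differed most at 48 h (SD over genes 0.38). The ribosomal protein median at 48 h turned from 0.26 to -0.12 after quantile normalization, and the cause was not tested. With the culture letter as a block the counts were 511, 1099, 1272, 2585 and 2473, and no named gene or list call changed. The letters alone may not mark linked cultures, since over 15 pairs of times the correlation across genes of the A minus B differences was between -0.20 and 0.34 with a median of 0.046. Signals near the constant of 10.2 are limited by background: HMOX1, ALAS2, CLU, IL1A, HSPA1L and TMEM176A started near or below it, and PIK3CG was below it at 6 h.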

Other observations

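The list tests in this part were planned, while the tests of MCM5 beside HMOX1 were chosen only after the result was seen, and the genes of the first paragraphs, RFC3 and TOM1 were chosen after their values were seen.

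Erythroid transcription factor genes were lower at 72 h than at 0 h: 0 of 12 tested genes rose, 6 fell and 6 did not pass (2 rose and 7 fell adjusted over the list alone), with median log2 change -0.60, camera adjusted p = 0.00162 and adjusted p = 0.0523 with an estimated correlation. KLF1 rose to 710.2 ± 19.3 at 12 h from 258 ± 50.8 at 0 h and was at 196 ± 20.5 at 72 h, with late minus early at -1.10 ± 0.11. KEL, a red cell surface gene, rose by 1.33 ± 0.20 at 6 h and was at -0.25 ± 0.20 at 72 h (adjusted p = 0.354), and LMO2 and MYB fell at 72 h, at -1.21 ± 0.20 and -1.40 ± 0.21. HBZ and HBB stayed above 0 h at 72 h, at 2.57 ± 0.13 and 1.82 ± 0.21, though the HBB probe set can bind transcripts of related genes.

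EGR1 went from 334 ± 21.3 at 0 h to 50.3 ± 1.56 at 12 h and 411 ± 79.6 at 72 h. GDF15 was at 276 ± 2.40 at 0 h, 93.2 ± 22.3 at 6 h and 1328 ± 24.8 at 72 h, and CHAC1 at 96.8 ± 12.5, 12.3 ± 0.778 and 147 ± 14.6 at these times. The hypoxia response list was higher late than early: 8 of 13 tested genes rose, 1 fell and 4 did not pass (8 rose and 1 fell adjusted over the list alone), with median log2 change 0.69, camera adjusted p = 0.00989 and adjusted p = 0.123 with an estimated correlation. TFRC fell 2.02-fold at 12 h (-1.01 ± 0.19), and the proteasome list rose at 24 h: 16 of 27 tested genes rose, 0 fell and 11 did not pass (19 rose and 0 fell adjusted over the list alone), with median log2 change 0.36, camera adjusted p = 2.27e-09 and adjusted p = 0.0668 with an estimated correlation.

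MCM5 rose by 3.02 at 72 h while the other 22 genes of the DNA replication list had a median of -0.21, with 3 rises and 8 falls and a highest value of 0.38 (RFC3), which argues against replication genes rising together. The signal of another gene in 1 probe set would leave the other MCM5 probe set near 0, but that one rose by 3.02 as well. In the GRCh38 gene order MCM5 follows HMOX1 on chromosome 22, and HMOX1 rose by 1.41 at 72 h. At 6, 12 and 24 h MCM5 had already risen by 1.24, 1.86 and 2.49, while HMOX1 was at 0.42 ± 0.33, 0.67 ± 0.33 and 0.63 ± 0.33 and was not called, which goes against transcription running on from HMOX1. HMOX1 signals were below 39.9 at these times and no reads beyond its end were measured, so this stays open. TOM1, on the other side of HMOX1, rose by 1.07 ± 0.21 (adjusted p = 0.00130) at 72 h.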
